A study of Mus musculus with 13 samples.

How the data were processed

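RNA was measured in 2 populations sorted from the pancreatic islets of NOD mice, an inbred strain that develops autoimmune diabetes. Per the labels, CD11c+ cells were sorted as live CD45+ cells that carried CD11c and MHC class II and lacked CD19 and CD90.2, and T cells as live CD45+ cells that carried CD90.2. Each replicate pooled 4 to 8 mice aged 12 to 20 weeks, per the series' design text. All mice received oral saline, per the labels' protocols. The sample names also carry the words vehicle and saline. The labels do not say whether these mark a difference in handling, and they were not compared. Libraries were made with a targeted amplicon kit that reads each gene through a single amplicon and were sequenced on an Ion Torrent instrument, per the labels' protocols and the file headers.

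The deposited tables hold raw counts of reads per amplicon target, not normalized, with 1 column per library and sequencing run. Per the labels' protocols the authors counted uniquely mapped reads, and per the submitters' processing notes the genome build was GRCm38 and DESeq2 was used, with no version stated. The mapper and its version are not stated. The tables list 23930 genes. In 27 rows the gene name had been turned into a date, and the name was restored from the target column. The 13 deposited samples are 9 libraries, because 4 libraries were sequenced in both run 133 and run 134. Their counts were summed over those runs, and the sums equalled the deposited combined table, with 0 cells that differed. Between the runs of 1 library, chi-square per degree of freedom was 1.57 to 2.37, against 54.4 to 601.0 between libraries of 1 group. The groups held 4 CD11c+ libraries and 5 T cell libraries, and runs of the same library were never counted as replicates.

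Total counts per library ran from 3271066 to 20856058. A count of 3 in a library, used as the floor, equals 0.144 to 0.917 CPM, here the counts scaled to each library's plain total. Amplicon reads carry no molecular identifiers, so floors and Wilson 95% intervals of shares cover counting error only. Counts were analysed in R 4.3.3. The main test was the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest) with TMM normalization and the default filterByExpr filter, with cell type as the only term, which left 12005 genes. Calls were made at a Benjamini-Hochberg adjusted p of at most 0.05. A log2 fold change is CD11c+ over T cells and is fitted with a prior count of 0.125. It is given with an approximate standard error (SE), the size of the change divided by the square root of the test's F statistic. Changes past 2-fold were tested with glmTreat on the same fit. CPM values of genes are means ± SD over the libraries of a group (n = 4 CD11c+, n = 5 T cells). They are scaled to a library's counts of tested genes times its TMM factor, 0.687 in CD11c replicate 2 to 1.317 in T cell replicate 5. The floor, the numbers of genes at 1 CPM, the test of genomic DNA and the strict filter use plain totals, so the scales differ. Every adjusted p given for a gene comes from this edgeR fit unless another test is named.

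Before the data were examined, 30 gene lists with 531 entries were fixed, of which 507 entries were on the panel. They cover the sort gate, chemokine ligands and receptors, integrins, adhesion molecules, lymphocyte egress, antigen presentation, costimulation, T cell and antigen-presenting cell programs, and markers of other cell types. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. The share of all counts held by 12 cell type marker lists was compared with a two-sided exact permutation test over the 126 splits of the libraries, adjusted over the 12 lists. The smallest p this design allows is 0.00794. Sets with a library left out allow fewer splits, so their smallest p is higher, and a call lost there need not mean a smaller difference. A set of ligand and receptor pairs was also fixed, of which 41 had both genes on the panel.

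The genes named in the report follow a rule fixed at the same time. It takes the 10 genes with the largest fold change in each direction among called genes with a mean of at least 50 CPM and no overlap between the groups. It also takes, per list, up to 4 called members in each direction and up to 2 members not called, with the highest CPM. Every gene of the sort gate, every chemokine ligand or receptor at 20 CPM or more in either population, and both genes of the pairs at 20 CPM were taken too. The report names part of the genes the rule names. 6 further gene lists, used only in the last part of the text, and the genes named from them were chosen after the results were seen. Gene positions and exon numbers come from GENCODE vM21 on GRCm38.

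The tests were tried on simulated data, with counts drawn from the real means and library sizes for 12005 genes, of which 200 were changed. In this simulated comparison, edgeR called 0% of 2-fold and 0% of 4-fold changes, 20.8% of 8-fold changes and 44.7% of 16-fold changes, and 0 of the 11498 unchanged genes that passed the filter. DESeq2 1.42.0 called 2.0%, 35.4%, 68.8% and 80.9%, and 41 unchanged genes. With only 200 genes changed, the adjustment of p was stricter than in the real comparison, where edgeR called 1796 genes. The means were pooled over both populations and no effect of the sort was drawn. These percentages are therefore no estimate of the power in the real comparison.

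By the library names in the sample descriptions, 4 sorts gave 1 library of each population. A sort means here the libraries that share the rest of the name, such as VEH_WAF. The sample titles write this part as vehicle or saline with 10x, wafergen or bulk. Libraries of the same sort deviated together from their group means, with correlations of 0.41, 0.36, 0.13 and 0.26, against -0.33 to 0.20 between libraries of different sorts. All 4 were over 0.1, the bound set for treating the sorts as pairs, although the labels do not state that a pair shares mice. A fit with the sort as a block was therefore run on the 8 paired libraries. The other alternatives were RLE size factors, TMM without islet endocrine and acinar genes, the DESeq2 Wald test, limma voom, no filter on low counts, a strict filter of 10 CPM in 4 libraries, either run alone, the deposited combined table, the sequencing run as a term, and each replicate left out. A fit without both libraries of the sort labelled VEH_WAF was added after the data were seen. For each gene level, library measure and marker share, the library farthest from its group was set against Dixon's critical value of 0.829 for 4 libraries and 0.71 for 5. Figures and artifact tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.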

Results

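Expression was measured by amplicon sequencing of 23930 genes in CD11c+ cells and in T cells sorted from the islets of NOD mice. The groups held 4 CD11c+ libraries and 5 T cell libraries, each from a pool of 4 to 8 mice aged 12 to 20 weeks. Total counts ran from 3271066 in CD11c replicate 2 to 20856058 in T cell replicate 5. The first principal component carried 46.6% of the variance and parted the populations. The second carried 21%, and on it CD11c replicate 2 and T cell replicate 3, both from the sort labelled VEH_WAF, lay apart from the other libraries of their groups. These 2 libraries also listed the most genes at 1 CPM, 14632 and 13419, against 9658 to 11242 in the other 7.

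**Figure D1:**
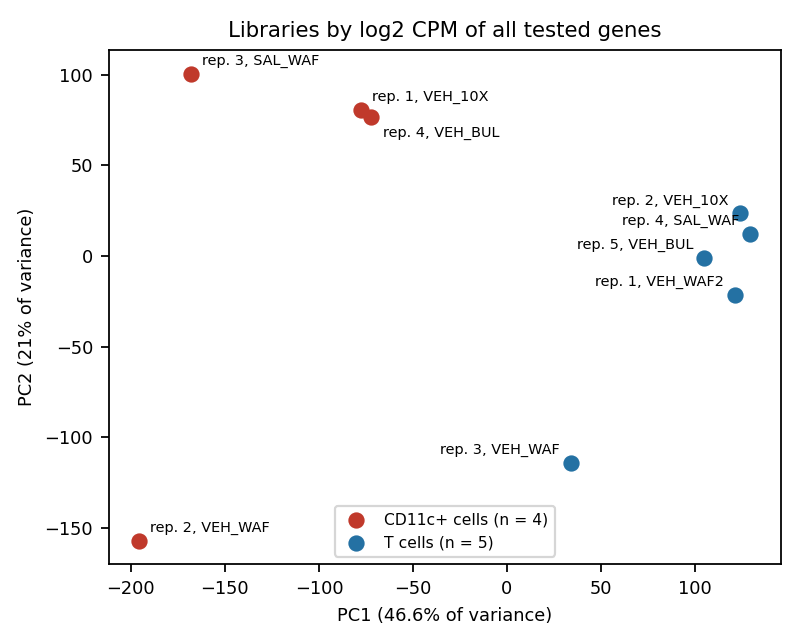
Principal components of log2 CPM of the tested genes, with the percent of variance on each axis. Each point is 1 library. The populations part on the first component (46.6%), and the VEH_WAF libraries lie lowest on the second (21%).

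The study compared the populations to ask what islet CD11c+ cells and islet T cells express, with lymphocyte trafficking molecules as the main family described here. The genes of the sort gate followed the labels. Itgax, which encodes CD11c, had 1406 ± 109 CPM in CD11c+ cells and 19.7 ± 26.3 CPM in T cells, and Cd74, the MHC class II invariant chain, had 59050 ± 15910 and 920.3 ± 1665 CPM. Thy1, which encodes CD90, had 12.9 ± 18.3 and 2222 ± 1145 CPM. Ptprc, which encodes CD45, had 490.2 and 480.1 CPM and a log2 fold change of 0.03 ± 0.68 (SE, edgeR adjusted p = 0.984). Cd19 stayed under the filter at 0.522 and 0.439 CPM. T cell replicate 3 held 3898 CPM of Cd74, against at most 207.7 CPM in the other T cell libraries. The gate list had 5 members higher in CD11c+ cells and 1 lower, with a camera adjusted p of 0.00268 and an adjusted p of 0.0955 with an estimated correlation.

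Of 12005 tested genes, edgeR called 1796, with 1230 higher in CD11c+ cells and 566 higher in T cells. Past 2-fold there were 843 and 342. The largest differences toward CD11c+ cells included Il12b, the shared subunit of interleukin-12 and interleukin-23, at 488.5 ± 304.2 CPM and a log2 fold change of 11.61 ± 1.15 (SE, edgeR adjusted p = 0.000176). They also included Ccl22 (10.53), the metalloprotease Mmp12 (10.46), the endotoxin co-receptor Cd14 (10.21), the phosphatidylserine receptor Timd4 (9.25) and the class Ib gene H2-M2 (9.06). The largest toward T cells included Ccr4 (-9.75), Gzmk (-9.68), Cd3e (-9.28), Cd3g (-9.19), Lck (-9.08), Themis (-9.03), Lef1 (-8.83) and Tnfsf11 (-8.77), as log2 fold changes. Folds of this size depend on the prior count, since the lower group was near the floor. Every CD11c+ value lay above every T cell value in 1372 genes and below in 1169, together 21.2% of the tested genes against 1.59% by chance. The calls rose to 2938 with the DESeq2 Wald test and to 2754 without the VEH_WAF libraries, a fit added after the data were seen. With the sort as a block, 343 genes were higher in T cells and 772 passed 2-fold, 204 of them higher in T cells. Without CD11c replicate 1, 321 genes were higher in T cells, 211 of them past 2-fold.

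More chemokine ligands were higher in CD11c+ cells than in T cells. Of 34 ligands on the panel 26 were tested, and 14 were higher in CD11c+ cells, 2 were higher in T cells and 10 were not called. Adjusted over the list alone, 16 and 2 were. The most abundant was Cxcl9, an interferon-induced ligand of CXCR3, at 5006 ± 2933 CPM in CD11c+ cells and 24.0 ± 25.9 CPM in T cells (log2 fold change 7.70 ± 1.26 SE, edgeR adjusted p = 0.00191). Cxcl10 had 1326 ± 776 and 172.4 ± 55.2 CPM (2.94 ± 0.55, adjusted p = 0.00401), and Cxcl11 had 67.9 and 1.72 CPM. Cxcl16, the ligand of CXCR6, had 1814 ± 403 and 7.75 ± 9.11 CPM (7.87 ± 1.03, adjusted p = 0.000538). Ccl3 had 1960 ± 2696 CPM, of which CD11c replicate 2 held 5996 and the others at most 849.1. Ccl4, Ccl17 and the neutrophil chemoattractant Cxcl2 were higher by 5.54, 6.91 and 7.29 on the log2 scale. Cxcl1 was higher by 5.05 (edgeR adjusted p = 0.0203) and lost its call with the sort as a block (adjusted p = 0.0532) and without T cell replicate 1 or 2 (0.0596 and 0.0564). The B cell attractant Cxcl13 had 635.5 ± 568.0 and 18.7 ± 23.1 CPM (adjusted p = 0.0146, and 0.0519 with the sort as a block). Ccl12, under the filter, had 51.8 CPM in CD11c+ cells and 0.0416 in T cells.

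T cells were higher in Xcl1, the ligand of XCR1, at 169.2 ± 42.0 CPM against 2.76 ± 4.14 (log2 fold change -6.17 ± 1.41 SE, edgeR adjusted p = 0.0123). Ccl1 was the other, at 11.4 and 1.56 CPM (adjusted p = 0.0461). That call was lost with the sort as a block (0.0863) and in 8 of the 9 fits that left out a library, all except that without CD11c replicate 2, with adjusted p up to 0.107. Ccl5 had 1790 ± 935 CPM in T cells and 761.0 ± 484.1 in CD11c+ cells (adjusted p = 0.16, and 0.0322 without the VEH_WAF libraries). Ccl8 had 602.6 ± 612.7 CPM in CD11c+ cells and 13.1 ± 28.3 in T cells (adjusted p = 0.0727, and 0.0152 with the sort as a block). T cell replicate 3 alone held 63.7 CPM of Ccl8, and without it the adjusted p was 0.000555. Ccl8 was also called with DESeq2 (0.017), limma voom (0.00426), no filter (0.0269), the run as a term (0.0384) and without the VEH_WAF libraries (0.000237). The ligand list was higher in CD11c+ cells by camera (adjusted p = 4.96e-07), with an adjusted p of 0.163 with an estimated correlation.

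**Figure D2:**
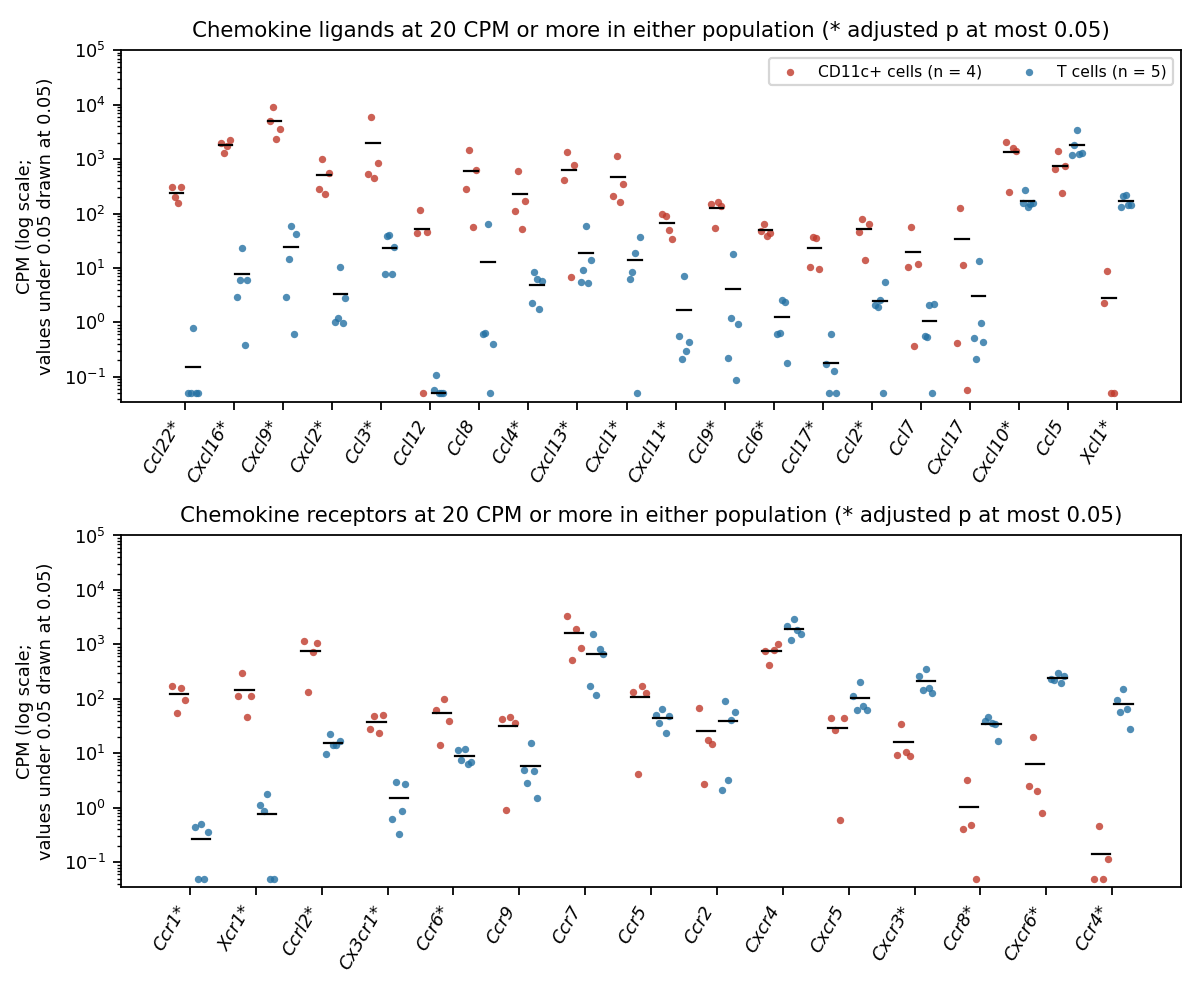
CPM on a log scale for each chemokine ligand (top) and receptor (bottom) at 20 CPM or more in either population. Points are libraries, bars are group means and stars mark edgeR calls. Cxcl9, Cxcl16 and Ccl22 lie higher in CD11c+ cells, and Cxcr3, Cxcr6 and Ccr4 higher in T cells.

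The receptors divided between the populations. Of 16 tested, 5 were higher in CD11c+ cells, 4 in T cells and 7 were not called (6 and 5 adjusted over the list alone), and the list had no direction by camera (adjusted p = 0.823). T cells were higher in Cxcr3, at 208.6 ± 94.0 against 15.95 ± 12.73 CPM (log2 fold change -3.73 ± 0.59 SE, edgeR adjusted p = 0.00156). Cxcr6 had 241.5 ± 42.5 against 6.29 ± 9.04 CPM (-5.38 ± 0.93, adjusted p = 0.00254), and Ccr4 79.1 ± 46.8 against 0.144 ± 0.218 CPM (-9.75 ± 1.07, adjusted p = 0.000236). CD11c replicate 2 held 19.8 CPM of Cxcr6 and 35.0 of Cxcr3, against at most 2.48 and 10.7 in the other CD11c+ libraries. Ccr8 was lower in CD11c+ cells by a log2 change of -5.40. CD11c+ cells were higher in Ccr1 (8.77), Xcr1 (7.55), Ccrl2 (5.61), Cx3cr1 (4.63) and Ccr6 (2.61). The call of Ccr6 had an adjusted p of 0.00988, and 0.0871 with the sort as a block. Cxcr4 had 1940 ± 680 CPM in T cells and 741.6 ± 241.2 in CD11c+ cells (adjusted p = 0.0503). Cxcr4 was called in 8 alternatives, with DESeq2 (0.00354), limma voom (0.0158), RLE size factors (0.0413), the strict filter (0.0441) and run 133 or 134 alone (0.0476 and 0.0461), without T cell replicate 3 (0.0491) and without the VEH_WAF libraries (0.0167). Ccr7 had 670.4 ± 583.8 and 1629 ± 1242 CPM, and Ccr5 44.5 ± 15.5 and 108.3 ± 72.1 CPM. Cxcr5 had 102.2 and 28.9 CPM. These 3 were not called, and without CD11c replicate 2 the adjusted p of Ccr5 was 0.0092, and without the VEH_WAF libraries 0.00322.

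Of the ligand and receptor pairs, 28 had at least 20 CPM of the ligand in CD11c+ cells and of the receptor in T cells. In 16 of them the ligand was higher in CD11c+ cells and the receptor higher in T cells. The bound of 20 CPM was set in this direction only, so it tends to remove pairs that run the other way. The 16 of 28 is therefore no measure of a preferred direction. They included Cxcl9, Cxcl10 and Cxcl11 with Cxcr3, Cxcl16 with Cxcr6, and Ccl17 and Ccl22 with Ccr4. They also held Icam1 with Itgal and the pairs of costimulation described further on. Xcl1 and Xcr1, which are not among the 28, ran the other way, with the ligand higher in T cells and the receptor in CD11c+ cells.

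On GRCm38, the genes of the CXCR3 ligands lie together on chromosome 5, Cxcl9 at 92321347 to 92328079, Cxcl10 at 92346638 to 92348889 and Cxcl11 at 92359544 to 92365485. The annotation gives Cxcl11 as a polymorphic pseudogene. Cxcr3 lies on chromosome X at 101731535 to 101734269. Cxcl16 lies on chromosome 11 at 70453983 to 70459984 and Cxcr6 on chromosome 9 at 123806475 to 123811760. Ccl22 lies on chromosome 8 at 94745590 to 94751699 and Ccr4 on chromosome 9 at 114490316 to 114504916. Vcam1 lies on chromosome 3 at 116109949 to 116129688. These genes other than Cxcl11 are annotated as protein-coding.

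Adhesion molecules differed in both directions. CD11c+ cells were higher in Vcam1, an endothelial and myeloid ligand of the integrin VLA-4, at 441.2 ± 228.8 against 10.4 ± 5.43 CPM (log2 fold change 5.41 ± 0.58 SE, edgeR adjusted p = 0.000224). Icam1, a ligand of LFA-1, had 410.8 ± 118.0 against 89.8 ± 31.3 CPM (2.19 ± 0.38, adjusted p = 0.00262). Sirpa, Cdh1 and Alcam were higher by 7.24, 3.61 and 2.12. T cells were higher in Cd2 (-7.97), Cd6 (-6.34) and Icam2 (-3.99). Icam2 lost its call without CD11c replicate 1 or 4 or T cell replicate 1, 2 or 5, with adjusted p up to 0.0834. Of 23 tested adhesion genes, 6 were higher in CD11c+ cells, 3 in T cells and 14 not called (7 and 3 adjusted over the list alone; camera adjusted p = 0.284). Of 22 integrins, 6 were higher in CD11c+ cells, 3 in T cells and 13 not called (7 and 6 adjusted over the list alone; camera adjusted p = 0.804, with a median log2 fold change of 0.00 and a mean of 0.68). The 6 integrins higher in CD11c+ cells include Itgax, a gene of the sort gate. Itgal, the alpha chain of LFA-1, had 692.1 ± 169.7 CPM in T cells and 174.8 ± 59.2 in CD11c+ cells (-1.99 ± 0.38, adjusted p = 0.00472). Itgb5 and Itga5 were higher in CD11c+ cells by 6.80 and 6.28. Itga4, the alpha chain of VLA-4, had 333.2 ± 96.9 CPM in T cells and 335.6 ± 207.6 in CD11c+ cells (adjusted p = 0.993). Itgb2 had 573.4 and 893.2 CPM (adjusted p = 0.212).

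The integrin calls of Itgae and Itga6 ended in some fits in which the fold stayed near its size. Itgae, higher in CD11c+ cells by 2.02 (edgeR adjusted p = 0.0195), had 2.21 and an adjusted p of 0.0801 with the sort as a block. Without CD11c replicate 1 or 4 or T cell replicate 1, Itgae had 1.94, 1.92 and 1.98 (adjusted p = 0.0633, 0.0630 and 0.0538), and with no filter on low counts 1.59 (0.128). Itga6, higher in T cells by a log2 change of -3.53 (adjusted p = 0.034), had -3.79 and 0.123 with the sort as a block. Without CD11c replicate 1 or 2 or T cell replicate 1, 2 or 4, Itga6 had -3.63 to -3.25 and adjusted p up to 0.0834.

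Among genes of egress from tissue, S1pr1, the receptor that guides lymphocytes out of lymphoid organs, had 422.1 ± 314.2 CPM in T cells and 4.24 ± 3.52 in CD11c+ cells (log2 fold change -6.58 ± 1.02 SE, edgeR adjusted p = 0.00143). S1pr4 was lower in CD11c+ cells by a log2 change of -5.17, and the oxysterol receptor Gpr183 higher by 2.84. Sgpl1, which degrades sphingosine-1-phosphate, was higher by 1.60 (adjusted p = 0.0356). The call of Sgpl1 was lost with the sort as a block (0.126) and in 7 of the 9 fits that left out a library, all except those without CD11c replicate 2 or T cell replicate 3. Of 13 tested genes of the list, 2 were higher in each population and 9 were not called (3 and 2 adjusted over the list alone; camera adjusted p = 0.731).

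CD11c+ cells were higher in MHC class II genes, while most MHC class I genes were not called. The cells were sorted for MHC class II, and H2-Aa, H2-Ab1, H2-Eb1 and Cd74 are also genes of the sort gate. The direction of the MHC class II list therefore followed from the sort. Of 13 MHC class II genes, 12 were higher and 1 not called (13 adjusted over the list alone; camera adjusted p = 1.52e-13, and 0.0381 with an estimated correlation). H2-Ab1 had 3362 ± 1272 CPM against 14.81 ± 24.95 (log2 fold change 7.83 ± 1.33 SE, edgeR adjusted p = 0.00234), and H2-Aa and the protease Ctss were higher by 6.19 and 4.08. Of H2-Ab1, T cell replicate 3 held 59.2 CPM and the other T cell libraries at most 6.82. The amplicon of H2-Eb1 gave only 7.43 CPM in CD11c+ cells. Reads that match several genes were not counted, so levels within families of near-identical genes, MHC genes included, are uncertain. Of 14 MHC class I genes, 2 were higher, Tapbp by 2.02 and Psmb10 by 2.01, and 12 were not called (5 adjusted over the list alone; camera adjusted p = 0.00303, and 0.0334 with an estimated correlation).

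Costimulatory ligands and their receptors lay on opposite sides. Of 13 ligands, 9 were higher in CD11c+ cells and 4 not called (10 adjusted over the list alone; camera adjusted p = 5.34e-06, and 0.0381 with an estimated correlation). Cd86 had 1138 ± 138 CPM against 28.8 ± 41.1 (log2 fold change 5.30 ± 0.86 SE, edgeR adjusted p = 0.00185). Of Cd86, T cell replicate 3 held 102.2 CPM and the other T cell libraries at most 12.3. Cd274, which encodes PD-L1, had 841.0 ± 336.7 against 205.8 ± 84.9 CPM (2.03 ± 0.45, adjusted p = 0.00995). Cd40, Icosl, Cd80, Tnfsf9 and Pvr were higher by 7.93, 5.18, 4.47, 3.95 and 2.72. Pdcd1lg2, which encodes PD-L2, was higher by 5.25 (adjusted p = 0.0244). Without T cell replicate 1, 2 or 5, Pdcd1lg2 had adjusted p of 0.0538, 0.0517 and 0.0586. Of 13 receptors, 11 were higher in T cells, 1 in CD11c+ cells and 1 not called (11 and 1 adjusted over the list alone; camera adjusted p = 6.39e-10, and 0.0229 with an estimated correlation). Ctla4 had 1535 ± 579 CPM in T cells against 4.72 ± 2.74 (-8.36 ± 0.79, adjusted p = 0.000145), and Pdcd1 1076 ± 397 against 55.9 ± 50.6 (-4.27 ± 0.71, adjusted p = 0.00205). Icos, Cd28, Tigit and Tnfrsf9 were at -6.14, -7.91, -7.62 and -4.63 on the log2 scale. Havcr2, which encodes TIM-3, was the receptor higher in CD11c+ cells, by 3.68.

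**Figure D3:**
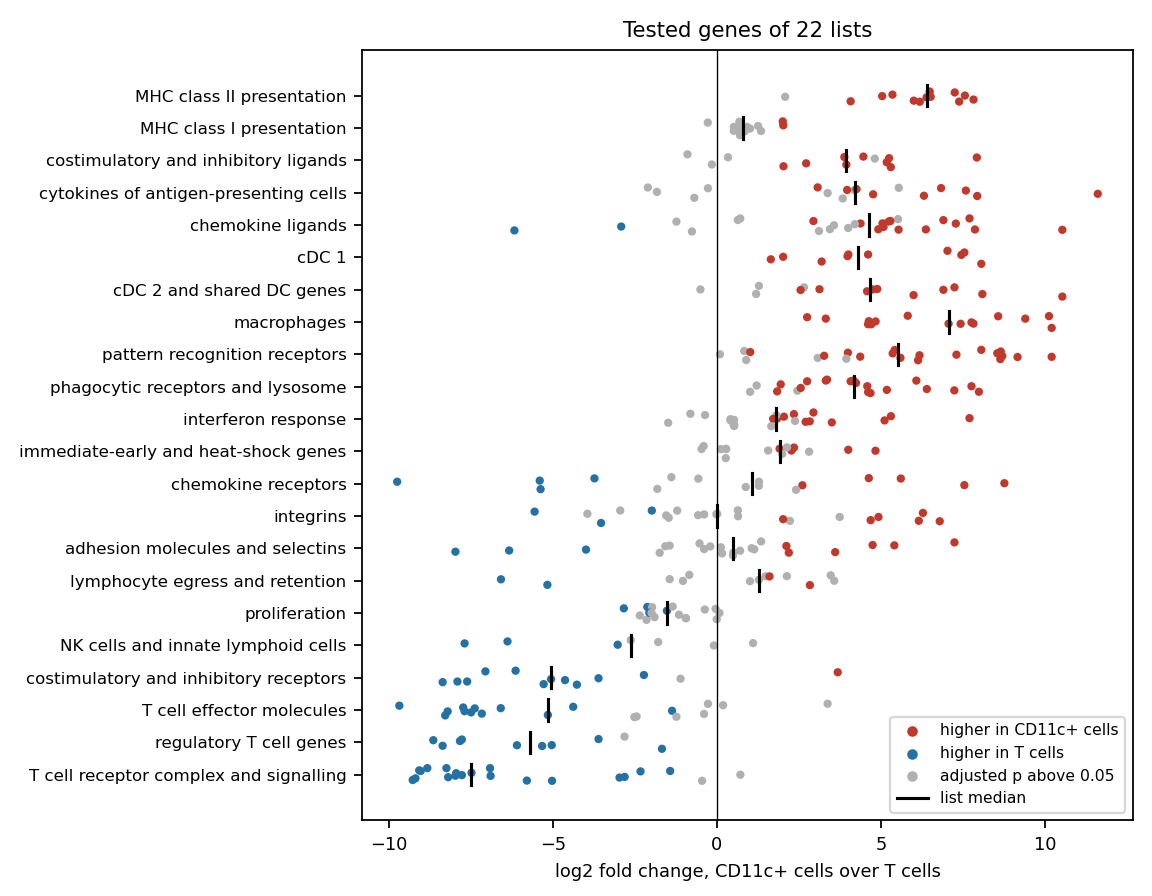
Log2 fold change (CD11c+ over T cells) of each tested member of the fixed gene lists. Points are genes, and their position to the right means higher in CD11c+ cells. MHC class II genes lie to the right (median 6.39) and T cell receptor genes to the left (median -7.48).

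T cells held the T cell receptor complex, with 19 of 21 tested genes higher and 2 not called (19 adjusted over the list alone; camera adjusted p = 6.08e-20, and 0.0147 with an estimated correlation). The 19 include Thy1, a gene of the sort gate. Cd3e had 1156 ± 400 CPM against 1.77 ± 1.34 in CD11c+ cells. Of 19 effector genes, 12 were higher in T cells and 7 not called (camera adjusted p = 6.39e-10, and 0.0334 with an estimated correlation). Adjusted over the list alone, 12 were higher in T cells and 1 in CD11c+ cells. Granzyme K (Gzmk) had 289.2 ± 125.4 against 0.404 ± 0.475 CPM, and Nkg7 and Gata3 were at -7.38 and -7.17. Ltb was at -1.37 (edgeR adjusted p = 0.0223), with adjusted p up to 0.067 without CD11c replicate 1 or 4 or T cell replicate 1 or 5. Il10 had 133.1 ± 74.5 CPM in T cells and 110.6 ± 142.5 in CD11c+ cells (adjusted p = 0.887). Of 10 regulatory T cell genes, 9 were higher in T cells and 1 not called (10 adjusted over the list alone; camera adjusted p = 6.5e-11, and 0.0334 with an estimated correlation). Foxp3, their lineage factor, had 330.8 ± 168.9 against 0.812 ± 0.395 CPM (-8.65 ± 0.73, adjusted p = 0.000119). Izumo1r and Tnfrsf18 were at -7.78 and -3.61.

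CD11c+ cells held genes of dendritic cells and of macrophages. All 10 genes of conventional dendritic cells 1 were higher (10 adjusted over the list alone; camera adjusted p = 6.94e-10, and 0.00854 with an estimated correlation). Irf8, their lineage factor, had 640.8 ± 128.9 CPM against 70.02 ± 39.95 (log2 fold change 3.19 ± 0.45 SE, edgeR adjusted p = 0.000826), and Wdfy4, needed for cross-presentation, and Cadm1 were higher by 7.46 and 4.61. Of 14 genes of conventional dendritic cells 2 and of dendritic cells in general, 10 were higher and 4 not called (10 adjusted over the list alone; camera adjusted p = 4.97e-09, and 0.0334 with an estimated correlation). Fscn1, Cd83 and Dpp4 were among them, by 4.58, 4.75 and 3.13. All 15 tested macrophage genes were higher (15 adjusted over the list alone; camera adjusted p = 5.6e-15, and 0.0334 with an estimated correlation). Lysozyme (Lyz2) had 4280 ± 982 against 18.9 ± 33.7 CPM (7.82 ± 1.55, adjusted p = 0.00555), the complement gene C1qb 1544 ± 825 against 8.92 ± 18.5 CPM, and the protease Ctsb was higher by 2.75. T cell replicate 3 held 78.8 CPM of Lyz2 and 42.0 of C1qb, against at most 9.16 and 1.61 in the other T cell libraries. Of 22 pattern recognition receptors, 17 were higher and 5 not called (19 adjusted over the list alone; camera adjusted p = 1.04e-13, and 0.0229 with an estimated correlation), with Nlrp3 (8.70), Clec7a (8.66) and Nod2 (6.18) among them. Of 21 genes of phagocytic receptors and lysosome, 18 were higher and 3 not called (19 adjusted over the list alone; camera adjusted p = 1.19e-15, and 0.0207 with an estimated correlation), with Psap at 4.17.

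Of 17 cytokine genes of antigen-presenting cells, 9 were higher in CD11c+ cells and 8 not called (13 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.41e-05, and 0.0902 with an estimated correlation). Il1b had 3894 ± 2272 CPM against 20.2 ± 41.8 (log2 fold change 7.59 ± 1.84 SE, edgeR adjusted p = 0.0164), and its antagonist Il1rn was higher by 7.94. Of Il1b, T cell replicate 3 held 94.9 CPM and the other T cell libraries at most 4.11. Il1a was higher by 6.84 (adjusted p = 0.0258), and without T cell replicate 1, 2 or 4 it had adjusted p of 0.0526, 0.0531 and 0.0502. Il18 was higher in CD11c+ cells by 3.07 and its receptor Il18r1 lower by a log2 change of -5.36. With the sort as a block their adjusted p were 0.0502 and 0.0586.

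Of 23 interferon response genes, 11 were higher in CD11c+ cells and 12 not called (11 adjusted over the list alone; camera adjusted p = 4.64e-05, and 0.0334 with an estimated correlation). Ly6a and Ifit1 were higher by 2.83 and 2.35, while Irf1 had 1063 ± 545 CPM against 739.7 ± 295.7 (edgeR adjusted p = 0.538). Of 17 proliferation genes, 4 were higher in T cells and 13 not called (9 adjusted over the list alone; camera adjusted p = 0.000831, and 0.174 with an estimated correlation). The replication factor Mcm6 had 648.6 ± 215.7 CPM in T cells against 90.6 ± 44.5 (-2.84 ± 0.47, adjusted p = 0.00197), with 1032 CPM in T cell replicate 3. Mcm2 was at -2.06, and with the sort as a block its adjusted p was 0.0604. The cell cycle genes Top2a and Ccna2 were at -2.12 and -1.52, with adjusted p of 0.0497 and 0.0288. Leaving out 1 library ended the call of Top2a in 7 of 9 fits, all except those without CD11c replicate 4 or T cell replicate 4, with adjusted p up to 0.111. The call of Ccna2 ended without CD11c replicate 1, 3 or 4 or T cell replicate 2 or 5, with adjusted p up to 0.081. With the sort as a block, Top2a had an adjusted p of 0.0735. Its log2 fold change was -1.41 without T cell replicate 3 and -1.4 without the VEH_WAF libraries. Of 15 immediate-early and heat-shock genes, 5 were higher in CD11c+ cells and 10 not called (8 adjusted over the list alone; camera adjusted p = 0.000875, and 0.0334 with an estimated correlation). Atf3, Zfp36 and Fos were higher by 4.84, 4.01 and 2.35.

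In all, camera called 14 of 29 lists higher in CD11c+ cells and 6 higher in T cells, and 10 and 5 with an estimated correlation. Some lists share genes, so these counts are not of independent lists. Of the genes on the panel, 9 of 20 for macrophages and 8 of 24 for phagocytic receptors and lysosome are also in another list. For the sort gate it is 7 of 8, while MHC class I presentation and costimulatory ligands share 0. The 14 lists higher in CD11c+ cells include those of the sort gate and of MHC class II, whose direction followed from the sort. Lists named for T cells, dendritic cells and macrophages describe the sorted cell types. Their directions are therefore no independent result either. Among 100 splits of the libraries, 11 gave 20 or more lists by camera with the preset correlation, the real one included, so this count of splits did not exclude chance for that number. The other 10 drew at least 3 of their 4 libraries from 1 population, so they carry part of the real difference. With an estimated correlation no other split called a list, but each of them mixed the populations within a group, so this is no measure of chance.

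Shares of the counts held by marker genes were compared for the sorted and for other cell types. Genes of the T cell receptor complex held 0.0593% ± 0.00459 of the counts in CD11c+ cells and 1.26% ± 0.0431 in T cells (SD, n = 4 and n = 5, two-sided exact permutation test, adjusted p = 0.019). Macrophage genes held 0.961% ± 0.246 and 0.0567% ± 0.0185 (exact permutation, adjusted p = 0.019), and genes of conventional dendritic cells 1 held 0.282% and 0.0349% (0.019). Genes of conventional dendritic cells 2 held 0.366% and 0.119% (0.0238), a call lost in 7 of the 9 sets that left out a library, all except those without CD11c replicate 2 or T cell replicate 2. These libraries overlapped, at 0.221% and 0.225%, and over the 9 sets the difference was 0.173 to 0.296 percentage points around 0.248. Natural killer and innate lymphoid genes held 0.0155% and 0.0945% (0.0238). Of 7 of these genes tested, 3 were higher in T cells and 4 not called (1 in CD11c+ cells and 4 in T cells adjusted over the list alone; camera adjusted p = 0.003, and 0.0334 with an estimated correlation), among them Eomes (-7.69), Klre1 (-6.39) and Rora (-3.03), which T cells can express too. By the labels the T cell gate was CD45 and CD90.2, with no marker that excludes natural killer or innate lymphoid cells. Whether such cells were in the T cell sort was not tested. Plasma cell genes held 0.0349% and 0.0904% (0.0238), a call lost without any 1 of the CD11c+ replicates (up to 0.134) and without the VEH_WAF libraries (0.0762). T cell replicate 3 held 0.179% of plasma cell genes against 0.0543 to 0.0751% in the other T cell libraries, and without it the difference went from -0.0555 to -0.0334 percentage points (0.0381). Jchain was the 1 plasma cell gene called of 6 tested (1 adjusted over the list alone; camera adjusted p = 0.113, and 0.0125 with no filter), at 337.8 ± 504.2 CPM in T cells against 10.9 ± 13.8 (edgeR adjusted p = 0.0474). Leaving out 1 library ended the call of Jchain in 7 of 9 fits, all except those without CD11c replicate 2 or T cell replicate 4. Its log2 fold change was -3.37 without T cell replicate 3, against -5.25 to -4.59 in the other fits among the 7.

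B cell genes held 0.00635% and 0.00231% (exact permutation, adjusted p = 0.019), with 0 of 7 tested genes called by edgeR (0 adjusted over the list alone; camera adjusted p = 0.0939, and 0.0461 with run 133 alone). Genes of neutrophils and mast cells held 0.0277% and 0.00121% (0.019), and only 2 of them passed the filter, 1 of them higher in CD11c+ cells (2 adjusted over the list alone), too few for camera. Plasmacytoid dendritic cell genes held 0.0722% and 0.0263% (0.0529, with 0.0381 without T cell replicate 3 and 0.0429 without the VEH_WAF libraries). Of 8 of them, 1 was higher in CD11c+ cells, Tcf4 by 2.85, and 7 were not called (1 adjusted over the list alone; camera adjusted p = 0.0173, and 0.314 with an estimated correlation). The call of Tcf4 (edgeR adjusted p = 0.0354) had an adjusted p of 0.0513 with the sort as a block. The call of Tcf4 was lost in 6 of the 9 fits that left out a library, all except those without CD11c replicate 2 or T cell replicate 3 or 4.

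Islet endocrine genes held 0.142% ± 0.14 of the counts in CD11c+ cells and 0.0796% ± 0.131 in T cells (exact permutation, adjusted p = 0.46). The endocrine share was higher in CD11c+ cells in all 4 sorts that gave both populations, and 4 pairs are too few for a two-sided exact p of 0.05. The shares were highest, with 0.342% in CD11c replicate 2 and 0.311% in T cell replicate 3, of the same sort. Insulin 2 had only 8.52 ± 5.02 CPM over the T cell libraries, so it made up little of the share in T cell replicate 3. The high shares of these libraries need not come from the same genes. Of 12 tested, 2 were higher in CD11c+ cells and 10 not called (2 adjusted over the list alone; camera adjusted p = 0.103, and 0.568 with an estimated correlation). The camera adjusted p of this endocrine list was 0.0212 with no filter on low counts, 0.0447 without CD11c replicate 3 and 0.0206 without T cell replicate 3. Insulin 2 (Ins2) had 754.7 ± 797.6 CPM against 8.52 ± 5.02 (log2 fold change 6.47 ± 0.88 SE, edgeR adjusted p = 0.000694), and the beta-cell peptide Iapp was higher by 3.72 ± 0.81. Somatostatin (Sst) had 891.9 ± 1298.0 against 387.3 ± 747.5 CPM (adjusted p = 0.59). It was higher in CD11c+ cells by 4.13 without T cell replicate 3 (adjusted p = 0.0216) and by 2.08 without the VEH_WAF libraries (0.0336), and had -0.63 without CD11c replicate 2 (0.813). Acinar and ductal genes held 0.0257% and 0.00315% (0.156), of which CD11c replicate 2 held 0.0898%, and were higher in CD11c+ cells in all 4 pairs too. Of 10 tested, 1 was called, Clps by 4.29 (0 adjusted over the list alone; camera adjusted p = 0.053, and 0.466 with an estimated correlation). The camera adjusted p of this acinar list, with the preset correlation, was 0.0192 with the sort as a block, 0.0256 with no filter, 0.0475 with the run as a term, and 0.034 and 0.0133 without CD11c replicate 1 or 3. Leaving out 1 library ended the call of Clps in 7 of 9 fits, all except those without CD11c replicate 3 or T cell replicate 3. Endothelial and stromal genes held 0.015% and 0.0345% (0.0667), with the lower share in CD11c+ cells in all 4 pairs. Of 10 tested, 1 was called, Kdr by 6.06 (1 adjusted over the list alone; camera adjusted p = 0.731), and the list's median of -0.75 and camera's direction differed in sign. Every T cell library (0.0188 to 0.0800%) held a higher endothelial share than every CD11c+ library (0.0130 to 0.0166%). Without any 1 T cell library the adjusted p of the endothelial share was 0.0381 to 0.0429, so these gained calls show no new separation. T cell replicate 5 held 0.0800%, and without it the difference in endothelial share went from -0.0195 to -0.00809 percentage points.

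**Figure D4:**
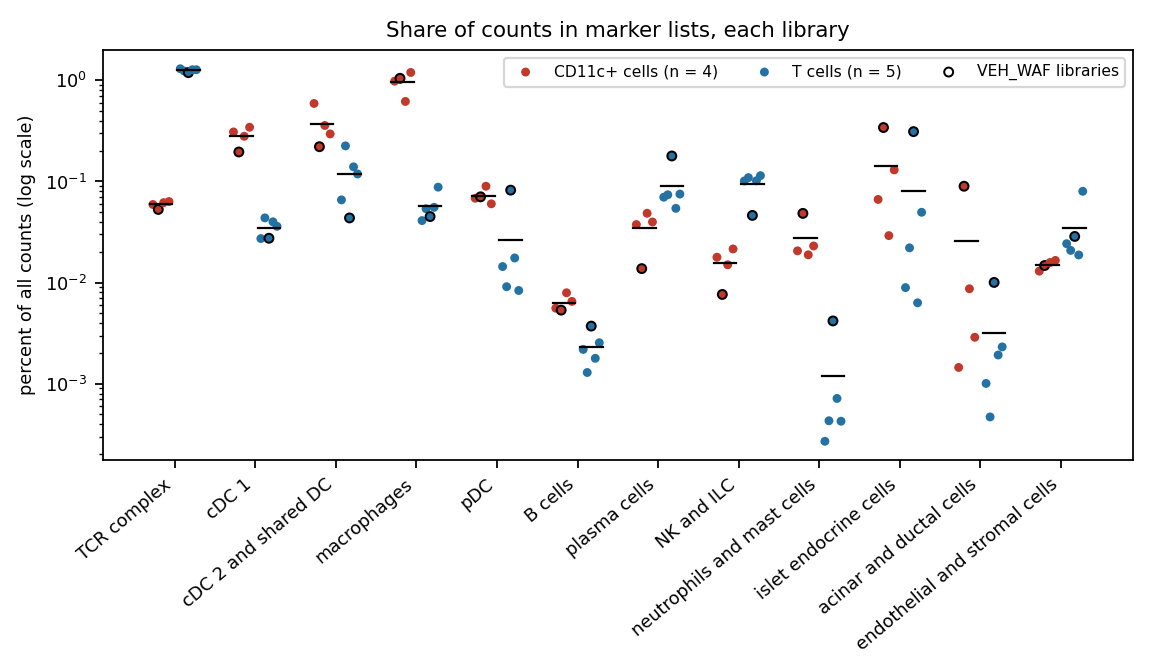
Percent of all counts held by 12 marker lists in each library. Points are libraries and bars are group means. T cell receptor genes hold 1.26% in T cells and 0.0593% in CD11c+ cells.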

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

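The tests of genomic DNA, of the sequencing run, of CD11c+ cells or their RNA in a T cell library and of insulin were written after the results were seen, and those of depth and of unrelated background before. The rules for CD11c+ cells in a T cell library and for endocrine cells were made stricter after their first results, which left both open, and the test of free islet RNA was set aside after its result. Values were listed here when the library farthest from its group passed Dixon's critical value, which 27 of 102 groups of values did. A rate of 1 in 20 would give 5.1, but that rate holds for independent, normally distributed values. These values were not on a log scale and came from the same 9 libraries, so 5.1 is not their chance rate. Of the 27, 25 lay in CD11c replicate 2 or T cell replicate 3, the libraries of the sort labelled VEH_WAF. Each is given as the ratio of the gap to the range, followed by the value of the library and those of the others.

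In T cell replicate 3, genes of CD11c+ cells lay above the other T cell libraries, in CPM: Itgax (0.737, 65.2 against 3.43 to 19.7), H2-Ab1 (0.893, 59.2 against 0.522 to 6.82), Cd74 (0.978, 3898 against 123.2 to 207.7) and Cd86 (0.943, 102.2 against 6.93 to 12.3). Il1b (0.957, 94.9 against 0.0435 to 4.11), Lyz2 (0.885, 78.8 against 0.0870 to 9.16) and C1qb (0.965, 42.0 against 0.131 to 1.61) did too. So did the chemokines Cxcl16 (0.758, 23.5 against 0.392 to 5.98), Ccl8 (0.99, 63.7 against 0 to 0.649), Cxcl13 (0.84, 59.6 against 5.40 to 14.0) and Ccl22 (1.0, 0.774 against 0). Ccl5, whose mean was higher in T cells than in CD11c+ cells, was high in this library too (0.715, 3403 against 1176 to 1810). Mcm6 had a ratio of 0.885 (1032 against 513.7 to 573.3).

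In CD11c replicate 2, Thy1 (0.843, 40.1 against 0.848 to 7.01 CPM), Cxcr3 (0.93, 35.0 against 8.83 to 10.7), Cxcr6 (0.912, 19.8 against 0.808 to 2.48) and Ccl3 (0.929, 5996 against 456.7 to 849.1) lay above the other CD11c+ libraries. Its share of T cell receptor genes was the lowest of the CD11c+ libraries, at 0.05292% against 0.05927 to 0.06335%. So was its share of natural killer and innate lymphoid genes, at 0.007643% against 0.01502 to 0.02153%. Cxcl10 had a ratio of 0.795 in T cell replicate 2 (269.1 against 130.0 to 158.4 CPM).

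Among shares of counts, T cell replicate 3 lay apart in genes of plasmacytoid dendritic cells (0.876, 0.0821% against 0.00837 to 0.0175%), plasma cells (0.833, 0.179% against 0.0543 to 0.0751%), neutrophils and mast cells (0.886, 0.00418% against 0.000270 to 0.000716%), endocrine cells (0.858, 0.311% against 0.00632 to 0.0496%) and acinar cells (0.807, 0.0101% against 0.000470 to 0.00232%). Its share of natural killer genes was low (0.81, 0.0462% against 0.101 to 0.114%). CD11c replicate 2 lay apart in neutrophil and mast cell genes (0.858, 0.0484% against 0.0188 to 0.0231%) and acinar genes (0.918, 0.0898% against 0.00145 to 0.00870%). The endothelial share was high in T cell replicate 5 (0.839, 0.0800% against 0.0188 to 0.0286%).

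CD11c replicate 2 and T cell replicate 3 listed more genes than the other libraries. The test of genomic DNA was first 1 joint test of both and was split by library after its result was seen. It asks whether single-exon genes silent elsewhere appear more often than multi-exon genes, and it argued against genomic DNA in CD11c replicate 2, with a ratio of 0.85 (95% interval 0.74 to 0.98). In T cell replicate 3 the ratio was 4.87 (4.51 to 5.26), which cannot tell, because CD11c replicate 1, without such an excess of genes, had 5.44. The shares themselves differed, with 73.0% of single-exon and 15.0% of multi-exon genes in T cell replicate 3 against 20.6% and 3.8% in CD11c replicate 1. CD11c replicate 2 had 30.1% and 35.4%, and the remaining libraries at most 7.1% of single-exon genes. The test set no bound on the shares, so genomic DNA in T cell replicate 3 stays open. The test of the run argued against it, as the SAL_WAF libraries of the same runs listed at most 10175 genes, and at 1 total count the VEH_WAF libraries still listed at least 14101 genes against at most 11709, so depth did not account for it either. No biological explanation, such as a difference between the pools of mice, was tested.

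Of 53 genes abundant in CD11c+ cells and low in the other T cell libraries, 90.6% were highest in T cell replicate 3, against at most 5.7% in any other T cell library, and 88.7% with genes picked from all 5 T cell libraries alike. They lay at a median of 2.72% of the CD11c+ level there, against 0.32% in the others. The excess grew with the CD11c+ level, by a ratio of 11.9, from 1.16 CPM in 1020 genes at 5 to 50 CPM and 7.52 CPM in 304 genes at 50 to 500 CPM to 13.8 CPM in 18 genes above, which argues against background unrelated to CD11c+ cells. Shares of marker lists showed no such rise. T cell replicate 3 held 0.0450% of macrophage genes, against 0.0411 to 0.0879% in the other T cell libraries. It held 0.0275% of genes of conventional dendritic cells 1 (others 0.0273 to 0.0437%) and 0.0436% of genes of conventional dendritic cells 2 (others 0.0658 to 0.225%). An addition of 2.72% of the CD11c+ share would be smaller than the spread among the other T cell libraries. With such an addition taken off, T cell replicate 3 would lie below every other T cell library in each of these lists. These shares come from a single library and do not decide the question. Whether CD11c+ cells or their RNA were in this library is left open, because the 90.6% met the test's bound of 90% on genes whose choice favours replicate 3 and the 88.7% did not, and no biological explanation was tested.

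Ins2 and Iapp were higher in CD11c+ cells. The smaller log2 fold change, that of Iapp, was 3.72, which is the pattern itself and decides nothing about free islet RNA. Endocrine cells of all kinds would raise the other endocrine genes by about as much, and the median of the other 10 was 0.17 (SD 2.69). Without T cell replicate 3, which held 0.311% endocrine counts, it was 2.16 (SD 1.99, 9 genes) beside 4.14 for Iapp, and without both VEH_WAF libraries 1.57 (SD 1.59, 9 genes) beside 4.23. This explanation and free islet RNA stay open, as does beta-cell material attached to or taken up by CD11c+ cells, which was not tested.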

How the results depend on the processing

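The splits with an estimated correlation and the fit without the VEH_WAF libraries were chosen after results were seen. Of the 134 called genes that the naming rule gives, 109 kept their call in each alternative that tested them and 25 lost it in at least 1, and none turned direction in those. Some genes were not tested in each, such as H2-Eb1, tested in 18 of 21. Of 29 gene lists, 21 kept their direction and side of the threshold in each alternative that tested them, which leaves out DESeq2, 3 lists under the strict filter and 1 without T cell replicate 3. Of 12 marker shares, 7 did, over the single runs, the combined table and the left-out libraries only. Numbers of genes moved by over 1.5 times in some alternatives, and the cause was not tested. DESeq2 called 2938 genes, 1190 higher in T cells, and 1767 of the 1796 main calls. Without the VEH_WAF libraries 2754 were called, 1149 higher in T cells and 561 of these past 2-fold. The part of calls higher in CD11c+ cells was 68.5%, and 59.5% with DESeq2 and 58.3% without the VEH_WAF libraries. With no filter on low counts, log2 fold changes shifted by a median of -0.317. Leaving out 1 library gave 1245 to 2307 genes, 895 to 1664 higher in CD11c+ cells and 321 to 691 in T cells, and 820 to 1444 past 2-fold, 211 to 409 of them higher in T cells. The lists called ranged from 20 to 22, and the chemokine ligands and receptors called from 21 to 27 around 25.

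With the sort as a block, 1257 genes were called, 343 of them higher in T cells, and 772 passed 2-fold, 204 of them higher in T cells. It kept 1164 of 1771 main calls and changed no call of a gene named in the report beyond those given there. The chemokine ligands higher in T cells were 1 with the block, with no filter, with the strict filter and with the run as a term, and 1 to 2 with a library left out. Other calls ended with limma voom (Cxcl13 0.0726, Il18r1 0.0874, Top2a 0.065), with no filter (Ccl1 0.0751, Clps 0.143, Il18 0.059, Sgpl1 0.124, Tapbp 0.0637, Tcf4 0.0876), with RLE (Jchain 0.0504), with run 133 alone (Jchain 0.057) and without the VEH_WAF libraries (Top2a 0.0851). With the run as a term they ended for Ccl1 (0.0577), Ccna2 (0.0768), Clps (0.0577), Icam2 (0.058), Ltb (0.0628), Sgpl1 (0.0995), Tcf4 (0.0809) and Top2a (0.0825).

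Lists without a call changed camera's direction in some fits. For a library left out, the range over all 9 fits is given, of which 1 to 5 changed direction or sign. Chemokine receptors did with no filter (adjusted p = 0.391), with the block (0.914) and with a library left out (0.551 to 0.909), and integrins with no filter (0.461), the strict filter (0.77) and a library left out (0.7 to 0.987). Lymphocyte egress did with no filter (0.868) and the strict filter (0.883), and endothelial genes with the block (0.773) and a library left out (0.349 to 0.9).

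Genes without a call and near 0 changed sign. The log2 fold change of Itga4 was -0.05 with RLE and with DESeq2, -0.10 with voom, -0.19 with no filter, -0.17 with the block, 0.00 with the run as a term and -0.35 to 0.34 with a library left out. That of Ptprc was -0.03 with RLE and with DESeq2, -0.30 with no filter, -0.15 without the VEH_WAF libraries and -0.37 to 0.29 with a library left out. With a library left out Il10 ran from -1.67 to 0.15 and Sst from -0.63 to 4.13, and the difference in endocrine share from -0.00436, without CD11c replicate 2, to 0.12. That in acinar share ran from 0.00119 to 0.0306 around 0.0225.

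The libraries were also split 100 ways into 4 and 5, the real way included. In 1 of 100 splits as many genes were called as in the real one, 1796, in 1 as many past 2-fold, 1185, and in 1 as many chemokine genes, 25, with 0 in every other split. Camera called 20 or more lists in 11 of 100, and up to 20 in the others of the 14 that part all 4 pairs, so this count of splits does not exclude chance for the number of lists. The other 10 drew at least 3 of their 4 libraries from 1 population, and splits with 2 CD11c+ libraries in the group of 4 reached at most 8 lists, so the counts carry part of the real difference and do not show what chance alone gives. With an estimated correlation 1 of 100 gave as many lists, 15, and every other split 0. Every split but the real one put both populations in at least 1 group, which widens the spread within it. The 0 calls of genes, of chemokine genes and of lists in the other splits therefore do not show what chance alone gives.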

Other observations

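The 6 gene lists of this part and the genes named from them were chosen after the results were seen, so their counts only describe the calls, and the camera tests run on them are not used. Of 20 tested genes of lipid handling, 11 were higher in CD11c+ cells and 9 not called, 3 of the 11 also in the lists fixed before. Among the higher genes were the lipid droplet gene Plin2 by a log2 fold change of 3.63, the cholesterol exporter Abca1 by 3.69, the sterol sensor Nr1h3 by 5.86 and the lipoprotein receptor Ldlr by 4.73. Of 17 matrix proteases and inhibitors, 8 were higher and 9 not called. Cst3, a protease inhibitor, had 8470 ± 2695 CPM against 209.3 ± 78.5, and Plau, Mmp14 and Adam8 were higher by 7.58, 4.85 and 3.95. Of 17 C-type lectins and Siglec receptors, 11 were higher, 1 lower and 5 not called (1 of the 12 also in the fixed lists), with Clec12a at 7.40. Of 11 complement genes, 3 were higher, among them Cfp at 4.99, 1 was lower and 7 were not called (1 of the 4 also in the fixed lists).

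Cytokine receptors divided between the populations, with 11 of 29 higher in CD11c+ cells, 4 in T cells and 14 not called (3 of the 15 also in the fixed lists). The decoy receptor Il1r2 had 2120 ± 1447 CPM in CD11c+ cells against 60.5 ± 34.8, and the receptor chains Csf2ra and Csf2rb were higher by 5.29 and 6.24. Il2rb had 1415 ± 433 CPM in T cells against 7.42 ± 4.48. Of 21 transcription factors of T cell memory and exhaustion, 8 were higher in T cells and 13 not called, and 4 of the 8 are also in the fixed lists, Tcf7 among them. Tcf7 had 1106 ± 648 CPM against 33.9 ± 12.6, and Tox, Ikzf3 and Foxo1 were at -6.01, -7.61 and -3.56 on the log2 scale.

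The RNA of the RNase P gene Rpph1 held 0.89 to 6.98% of the counts of a library, the most in T cell replicate 3. The amplicons of C1qa, C1qc and Ins1 gave means of 1.52, 7.92 and 0.913 CPM in CD11c+ cells, although C1qb and Ins2 were abundant in CD11c+ cells.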
